A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

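The series holds 18 arrays of total RNA from Saccharomyces cerevisiae, in 9 groups of 2: 3 strains (a haploid labelled alpha, a haploid labelled a, a diploid), each at 0%, 3% and 7% ethanol. The deposited values are an intensity per probe set, made per the labels by the Affymetrix GCOS software from biotin-labelled RNA hybridised to 1 array per sample. The GCOS version, the signal settings and any scaling target are not given in the sources used here. The values were linear and the 2% trimmed mean of the S. cerevisiae probe sets ranged from 368.5 to 521.5 between arrays, more than the 10% set as the limit before the data were examined. Each array was therefore multiplied by a factor of 0.84 to 1.19 to give the same trimmed mean, and 16 was added before log2.

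The array carries 10928 probe sets. Of these, 5498 read 1 S. cerevisiae gene in the annotation, 1746 read a gene of another yeast and 166 are controls. The background limit of an array was the 95th percentile of its probe sets for the other yeast, which was 4.6 to 7.58 in scaled signal. A gene entered when its probe set exceeded that limit on at least 2 arrays. 5363 of 5449 genes entered and 86 did not. Where a gene had several probe sets, the brightest on average stood for it. 105 of the genes tested had a probe set that reads related genes too, and these are named as such in the results. 12 gene symbols were updated through the annotation. Left out were controls, probe sets annotated to the other yeast and 3470 probe sets without a gene name, whose number past the threshold is given among the closing observations. The annotation does not give the species of these 3470, so they may include probe sets of the other yeast.

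A mean per group was fitted to all 18 arrays with limma 3.58.1 (lmFit, then eBayes with an intensity trend; R 4.3.3, statmod 1.5.0), which leaves 9 residual degrees of freedom. There were 16 contrasts: 3 pairs of ethanol levels in the mean of the strains, 3% and 7% against 0% within each strain, the diploid against the mean of the haploids over all levels and at 0%, the haploid strains against each other, and 4 differences of ethanol changes between strains. Adjusted p-values are Benjamini-Hochberg values over the 5363 genes within a contrast, two-sided, with a threshold of 0.05. A fold is given as a lower bound when a gene lay at or under the background limit on all arrays of 1 side. The spread between the arrays of a group was pooled over the 9 groups, with SD from 0.112 to 0.156 and Pearson r across genes from 0.9929 to 0.9963. The ratio of the 3' to the 5' control of ACT1 was 1.09 to 1.3, and the signal of the 18S rRNA control ranged from 395.6 to 1886.

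Before the data were examined, 39 gene lists were fixed, and 834 of their genes were among those tested. They cover a-specific, alpha-specific, haploid-specific, pheromone, meiosis, ploidy-dependent and daughter separation genes, and the Gcn4, sulfur, ergosterol, fatty acid and phospholipid genes. They also cover heat shock chaperones, the endoplasmic reticulum response, general stress (Msn2 and Msn4), oxidative defence, trehalose, glycogen, glycerol, glycolysis, ethanol and acetaldehyde metabolism, the citric acid cycle, the respiratory chain and the mitochondrial ribosome. The rest are ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, histones, the cell wall, flocculation, hexose and drug transporters, glucose-repressed, iron, phosphate and thiamine genes, the proteasome, the vacuolar ATPase and reference genes. Each list was tested with limma's camera at a preset correlation of 0.01, with a second run at a correlation estimated from the data, and adjusted over the 39 lists of a contrast. A call means an adjusted p under the threshold at the preset correlation. Camera sets the genes of a list against all other genes, so a list called higher or lower is so relative to those genes. Counts of rises and falls in a list are over all genes tested, and a count adjusted over the list alone is given where it differed.

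The genes named follow a rule fixed before the data were examined. In contrasts that average over strains or levels they are the 10 largest rises and 10 largest falls past the threshold with the same sign in each of the 3 strains or levels. In the other contrasts they are the 3 largest in each direction. From each list described they are up to 4 members with the smallest adjusted p and the exceptions in direction, and the mating-type lists may be named in full. The text names a part of these.

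The fit was tested on simulated data for 5363 genes, of which 100 were given a change of 1 and 100 a change of 0.5. Errors were independent between genes and no scaling step was simulated. The rates that follow therefore do not cover correlated genes, the scaling or contrasts in which a large share of genes changed. In the mean of the strains at 7% against 0%, 100% of genes given a change of 1 and 94% of those given 0.5 were recovered, with 5.83% false calls. Within 1 strain these were 100%, 76% and 5.38%. Replicate numbers were checked for pairing: the correlations of replicate differences between the 36 pairs of groups were -0.25 to 0.18, with a median of 0.047 and 11 above 0.1. No block was fitted. Log2 18S signal of replicate 1 minus replicate 2, at 3% and 7%, was 1.7 and 1.4 in the strain labelled alpha. It was -1.87 and -1.37 in the strain labelled a and -0.17 and -0.42 in the diploid. A batch that runs across replicate numbers was not tested. Alternatives planned were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at 2 times the background limit, the mean of a gene's probe sets, no intensity trend, array weights, only the groups compared, the replicate block, each array left out in turn and the estimated correlation. Unscaled values, the 18S rRNA signal as a covariate and leaving out each haploid strain were chosen after seeing the data. For 5 contrasts the arrays were also split at random into groups of the same sizes 100 times, the other factor as a covariate.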

Results

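RNA levels were measured on 18 Affymetrix yeast arrays, 1 for each sample of total RNA. The samples came from 3 ethanol-tolerant strains of Saccharomyces cerevisiae: a haploid labelled alpha, a haploid labelled a, and a diploid. Each strain grew in fermentors in rich glucose medium that held 0%, 3% or 7% ethanol by volume, and cells were taken in exponential growth. Each strain and ethanol level has 2 samples. The labels do not say whether these came from separate cultures, so the errors below cover what differs between the samples, whatever that is. For arrays, their number limits the precision: the SD between the 2 arrays of a group was 0.112 to 0.156 on the log2 scale. Of the 5363 genes tested, 5229 to 5333 lay above the background limit of an array. Changes are given as log2 differences ± SE of the fit. These and the folds beside them are of the scaled signal plus 16, so for dim transcripts they are smaller than the ratio of the signals. The words "rose", "fell", "higher" and "lower" are used of genes past the adjusted p threshold of 0.05.

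The strain labelled a had the alpha-specific transcripts of an alpha cell. MF(ALPHA)1, which encodes the pheromone alpha factor, had a mean signal of 4670 ± 359 (SD, n = 6 arrays) in the strain labelled a and 4390 ± 424 in the strain labelled alpha. In the diploid it was 14.8 ± 2.54. STE3, the receptor for a-factor, read 1250 ± 481, 1760 ± 450 and 7.69 ± 2.23 in the strain labelled a, the strain labelled alpha and the diploid. The probe set that reads the alpha1 regulator, shared by the mating-type locus and its silent copy HMLALPHA1, read 581 ± 63.2, 606 ± 61.3 and 16.6 ± 3.38 in the same order. The 7 a-specific genes, such as MFA1 and STE2, had mean signals of 7.33 to 30.8 in the strain labelled a, 5.21 to 25.4 in the strain labelled alpha and 4.49 to 27.5 in the diploid. At these low levels 3 of the 7 were higher in the strain labelled a than in the strain labelled alpha and 0 lower, without a call for the list (adjusted p = 0.283). AGA2, an agglutinin subunit, read 15.3 ± 4.24 in the strain labelled a, 5.21 ± 1.34 in the strain labelled alpha and 4.49 ± 2.04 in the diploid, and lay above the background limit on 6, 2 and 3 of 6 arrays. MFA1 read 18.8 ± 5.64, 8.63 ± 4.88 and 7.69 ± 3.58. The third was MFA2, at 30.8 ± 9.86, 21.5 ± 4.39 and 19.9 ± 6.3. HMRA1, whose probe set reads the a1 regulator, lay above the background limit on 0 of 6 arrays of the strain labelled a, 0 of 6 of the strain labelled alpha and 6 of 6 of the diploid. The 13 haploid-specific genes had a median signal of 337 in the strain labelled alpha, 240 in the strain labelled a and 13.7 in the diploid. As its alpha-specific and HMRA1 levels are at odds with the a label, "the strain labelled a" is used throughout.

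**Figure D1:**
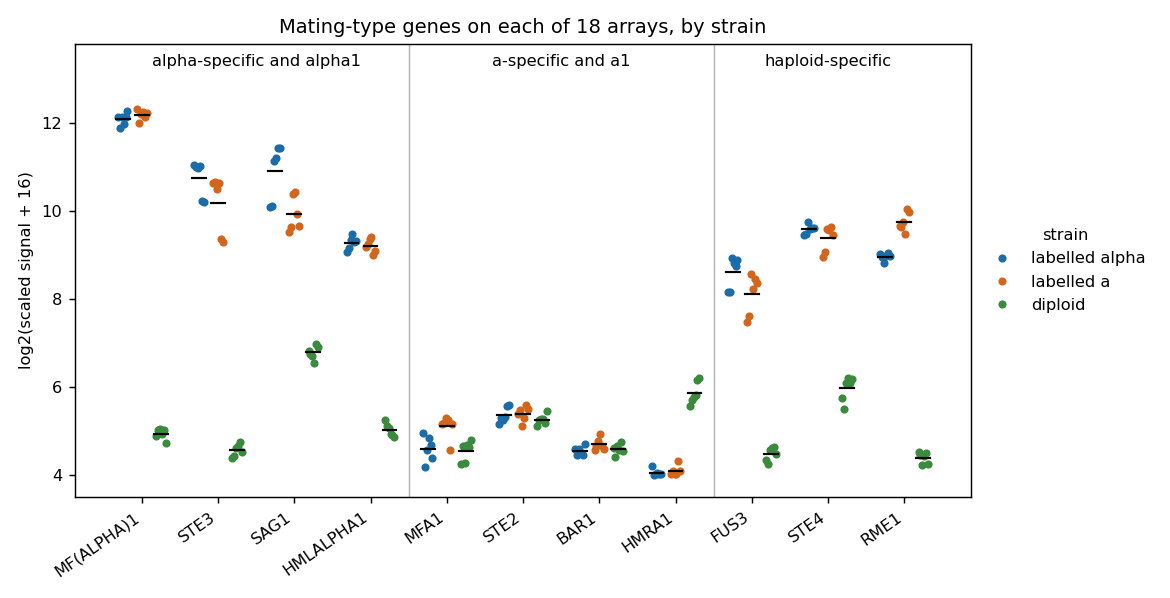
Log2 of the scaled signal plus 16 for 11 mating-type genes on each of the 18 arrays; points are arrays, bars are the mean of the 6 arrays of a strain. The alpha-specific genes are high in both haploid strains, including the strain labelled a, and low in the diploid, where HMRA1 is detected.

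Cells growing in 7% ethanol had more transcripts for assembling ribosomes, and fewer for making amino acids, than cells of the same strains in 0%. HSP26 (YBR072W), a small heat shock protein that holds unfolding proteins, rose by 3.34 ± 0.059 as the mean of the 3 strains, which is 10.1-fold (adjusted p = 4.07e-20). CIT2 (YCR005C), the peroxisomal citrate synthase, rose by 3.20 ± 0.064 and YRO2 (YBR054W), a plasma membrane protein, by 3.17 ± 0.051. SRY1 (YKL218C), which breaks down hydroxyaspartate, fell by 3.20 ± 0.05 (9.2-fold lower), and SER3 (YER081W), the first enzyme of serine synthesis, fell by 2.86 ± 0.061 (7.27-fold lower). In the mean of the strains 2591 genes rose and 1196 fell. Changes of at least 2-fold were fewer, 337 up and 153 down.

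Besides HSP26, CIT2 and YRO2, the largest rises at 7% ethanol that had the same direction in each strain included NCA3, 2.93 ± 0.059, and GIT1, a transporter of glycerophosphoinositol, 2.86 ± 0.082. GIT1 is dim at 0%, and its change was 4.48 with a pseudocount of 1. INO1, which makes inositol phosphate, rose by 2.55 ± 0.096, GSC2, a subunit of glucan synthase, by 2.52 ± 0.053 and CHA1, a serine and threonine deaminase, by 2.51 ± 0.064. CLN2, a G1 cyclin, rose by 2.23 ± 0.067 and ARX1, an export factor of the large ribosomal subunit, by 2.18 ± 0.06. The largest falls after SRY1 were in the cell wall gene PRY3 (-3.07 ± 0.092) and in SER3, HIS5 (-2.66 ± 0.059) and the hexose transporter HXT2 (-2.62 ± 0.065). AQR1, a membrane exporter, changed by -2.58 ± 0.088, TMT1 by -2.56 ± 0.064, the butanediol dehydrogenase BDH1 by -2.53 ± 0.047, STR3 of methionine synthesis by -2.44 ± 0.055 and the drug transporter QDR2 by -2.28 ± 0.112.

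The genes that assemble ribosomes rose together at 7%: 60 of 60 measured members of the ribosome biogenesis list rose and 0 fell, with a median change of 1.30 (camera adjusted p = 3.02e-18; 0.0454 with an estimated correlation). NSR1 rose by 1.93 ± 0.057, RLP24 by 2.02 ± 0.059 and YTM1 by 2.05 ± 0.067. Among the subunits of RNA polymerases I and III, 18 of 19 rose, RPA135 by 1.28 ± 0.055 and RPA43 by 1.48 ± 0.065 (adjusted p = 5.14e-06). That call was lost at adjusted p = 0.0563 with an estimated correlation. Of 55 proteins of the mitochondrial ribosome 49 rose and 1 fell, with MRP13 at 0.93 ± 0.063 and MRPL15 at 0.76 ± 0.057 (adjusted p = 4.12e-05), lost at adjusted p = 0.313 with an estimated correlation. The cytoplasmic ribosomal protein list was not called: 23 of 128 rose and 7 fell, and with median centring 1 rose and 98 fell. Its counts here and below include RPP1 (YHR062C), a subunit of RNase P that is not a ribosomal protein.

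Chaperones under the heat shock factor, membrane phospholipid genes and genes of the unfolded protein response had list calls at 7% that were lost with an estimated correlation. Of 24 chaperone genes 19 rose and 1 fell, with HSP82 at 1.31 ± 0.05, its partner CPR6 at 0.94 ± 0.045 and the mitochondrial HSP78 in the other direction at -1.18 ± 0.061 (adjusted p = 0.00642; adjusted p = 0.105 with an estimated correlation). Of 12 phospholipid genes controlled through inositol 11 rose and 0 fell, with OPI3 at 0.99 ± 0.044, CHO1 at 0.83 ± 0.048 and the regulator INO2 at 1.11 ± 0.068 (adjusted p = 0.00642; adjusted p = 0.0563 with an estimated correlation). Of 15 genes of the endoplasmic reticulum response 13 rose and 0 fell, ERO1 by 1.13 ± 0.073 and KAR2 by 0.53 ± 0.042 (adjusted p = 0.00994; adjusted p = 0.0612 with an estimated correlation). A list of 7 genes that depend on ploidy in other strains had 6 rises and 1 fall, with CLN1 at 1.17 ± 0.063 and GIC2 at 1.46 ± 0.058 (adjusted p = 0.018; adjusted p = 0.25 with an estimated correlation). The chaperone, endoplasmic reticulum and ploidy calls also ended without the strain labelled alpha.

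Amino acid, sulfur and ergosterol genes fell as groups at 7%. Of 41 amino acid genes under the activator Gcn4, 38 fell and 1 rose, with a median of -0.80 (camera adjusted p = 8.29e-27; 0.0103 with an estimated correlation). HIS4 changed by -2.20 ± 0.04 and LYS1 by -2.02 ± 0.049. Of 23 genes of sulfur and methionine metabolism 18 fell and 2 rose, with MUP1, a methionine transporter, at -1.45 ± 0.046 and MET13 at -1.67 ± 0.065 (adjusted p = 4.58e-10; 0.0129 with an estimated correlation). Of 22 ergosterol genes 19 fell and 1 rose, with ERG4 at -1.85 ± 0.045 and HMG1 at -1.14 ± 0.065 (adjusted p = 1.34e-07; 0.0129 with an estimated correlation).

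Smaller groups fell at 7% with calls that did not hold with an estimated correlation. Of 16 drug transporter genes 8 fell and 4 rose, with SNQ2 at -1.68 ± 0.05, PDR12 at -1.78 ± 0.062 and PDR5 at -1.38 ± 0.054 (adjusted p = 0.00494; adjusted p = 0.229 with an estimated correlation). Of 14 hexose transporters 8 fell and 1 rose, and the riser was HXT7 at 1.16 ± 0.095, whose probe set also reads a related gene (adjusted p = 0.00642; adjusted p = 0.183 with an estimated correlation). Of 11 glycogen genes 7 fell and 2 rose, with GSY1 at -1.78 ± 0.055 (adjusted p = 0.0173; adjusted p = 0.16 with an estimated correlation). Of 7 trehalose genes 4 fell and 1 rose, with TSL1 at -1.20 ± 0.047 (adjusted p = 0.0262; adjusted p = 0.302 with an estimated correlation). Of 16 genes of the citric acid cycle 8 fell and 3 rose, with SDH1 at -0.82 ± 0.057 and CIT1 at 0.58 ± 0.042 (adjusted p = 0.0216; adjusted p = 0.181 with an estimated correlation). The trehalose and citric acid cycle calls also ended with quantile normalization, without scaling between arrays and without the strain labelled a, and the trehalose call with median centring.

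The general stress genes under Msn2 and Msn4 split at 7%: of 30, 13 rose and 12 fell, with SPI1 at 2.12 ± 0.055 and PGM2 at -1.44 ± 0.048, and the list was not called. The other lists without a call had these counts of rises and falls: haploid-specific 7 and 0 of 13, cell wall 16 and 4 of 27, phosphate 10 and 4 of 14, alpha-specific 1 and 3 of 5, a-specific 1 and 0 of 7, pheromone response 8 and 4 of 15. Respiratory chain genes had 17 and 2 of 31, oxidative defence 7 and 9 of 24, meiosis 12 and 2 of 22, daughter cell separation 4 and 4 of 10. Iron genes had 6 and 3 of 16, histones 4 and 0 of 7, glycolysis 3 and 4 of 16, ethanol and acetaldehyde metabolism 7 and 5 of 16, fatty acids 7 and 1 of 12. The proteasome had 17 and 5 of 35, the vacuolar ATPase 7 and 2 of 19, thiamine 8 and 3 of 16, glycerol 4 and 2 of 10, flocculation 2 and 1 of 4. Genes repressed by glucose, such as HXK1 at 1.63 ± 0.039, had 8 and 7 of 21, and the reference genes 3 and 2 of 8. When adjusted over the list alone, 19 RNA polymerase genes rose, 50 mitochondrial ribosome genes rose, 19 sulfur genes fell, 14 general stress genes rose, 0 a-specific genes rose, 12 ribosomal protein genes rose and 4 fell, and 6 fatty acid genes rose.

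The balance of rises and falls depends on the scaling between arrays. The median of all genes was 0.13 higher at 7% than at 0%, and 1865 genes rose and 1845 fell with quantile normalization, 1619 and 2208 with median centring. With median centring of each array, the list medians were 1.10 for ribosome biogenesis, 0.73 for the polymerases, 0.25 for the mitochondrial ribosome, 0.18 for chaperones, -1.01 for amino acids, -0.95 for sulfur and -0.50 for ergosterol.

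**Figure D2:**
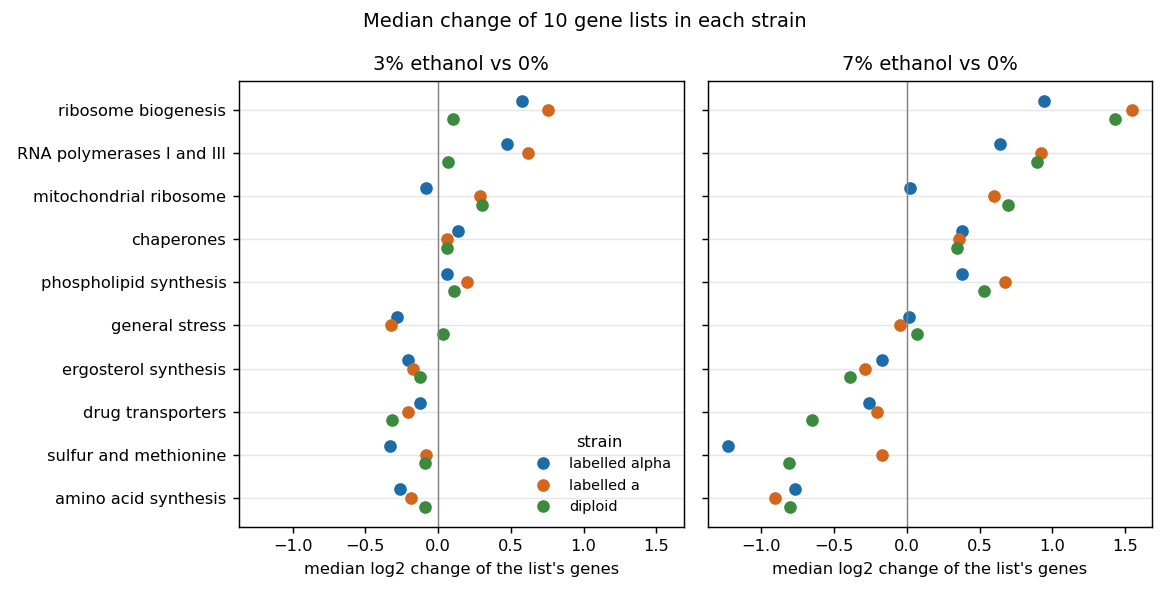
Median log2 change of the genes of 10 lists in each strain, at 3% ethanol (left) and 7% ethanol (right) against 0%; each point is 1 strain. Ribosome biogenesis lies at 0.95 in the strain labelled alpha, 1.55 in the strain labelled a and 1.43 in the diploid at 7%, and amino acid synthesis at -0.77, -0.91 and -0.80.

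At 3% ethanol fewer genes changed by at least 2-fold, and in the mean of the strains ribosome assembly genes rose while general stress and glycogen genes fell. In the diploid alone, ribosome biogenesis (6 rises and 2 falls of 60), general stress (6 rises and 1 fall of 30) and glycogen (0 rises and 2 falls of 11) were not called. YRO2 rose by 1.75 ± 0.051 (3.37-fold) as the mean of the 3 strains, PHO84, a phosphate transporter, by 1.52 ± 0.062 and HSP26 by 1.36 ± 0.059 (2.56-fold). AQR1 fell by 1.88 ± 0.088 (3.68-fold lower) and HXT2 changed by -1.80 ± 0.065. In all, 1715 genes rose and 929 fell, 20 and 16 of them by at least 2-fold. With quantile normalization the counts were 1237 and 1209, with median centring 1168 and 1313.

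Other large rises at 3% were in GPM2, a relative of phosphoglycerate mutase, at 1.35 ± 0.064 and in YAR009C, a retrotransposon gene whose probe set reads several copies, at 1.77 ± 0.309. Other large falls were in QDR2 (-1.42 ± 0.112), HXT1 (-1.34 ± 0.1), BDH1 (-1.28 ± 0.047), the siderophore transporter ENB1 (-1.23 ± 0.098) and HXT3 (-1.18 ± 0.036). Of 60 ribosome biogenesis genes 59 rose and 0 fell, with a median of 0.50, DBP3 at 1.12 ± 0.066 and RLP24 at 0.79 ± 0.059 (adjusted p = 3.37e-17; 0.0411 with an estimated correlation). Of 30 general stress genes 18 fell and 5 rose, with MSC1 at -0.71 ± 0.052, PGM2 at -0.66 ± 0.048 and HXK1 in the other direction at 0.58 ± 0.039 (adjusted p = 6.59e-06; 0.0123 with an estimated correlation). Of 11 glycogen genes 8 fell and 0 rose, with GPH1 at -0.78 ± 0.055 (adjusted p = 4.01e-05; 0.0396 with an estimated correlation). Of 16 citric acid cycle genes 8 fell and 2 rose, with IDH2 at -0.46 ± 0.039 and ACO1 at -0.43 ± 0.039 (adjusted p = 5.86e-05; 0.0396 with an estimated correlation). Of 22 ergosterol genes 15 fell and 2 rose, with ERG4 at -0.62 ± 0.045 and HMG1 at -0.69 ± 0.065 (adjusted p = 6.59e-06; 0.0396 with an estimated correlation).

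A further 8 lists were called at 3% but lost their call with an estimated correlation. Of 41 amino acid genes 27 fell and 6 rose, with LYS1 at -0.68 ± 0.049 and ARG3 at 1.06 ± 0.046 (adjusted p = 1.42e-08; adjusted p = 0.0517 with an estimated correlation). Of 19 RNA polymerase genes 16 rose and 0 fell, RPA190 by 0.52 ± 0.053 (adjusted p = 1.3e-05; adjusted p = 0.0517 with an estimated correlation). Of 23 sulfur genes 12 fell and 0 rose, with MUP1 at -0.75 ± 0.046 (adjusted p = 6.44e-05; adjusted p = 0.0517 with an estimated correlation). Of 16 drug transporter genes 9 fell and 1 rose, with TPO4 at -0.88 ± 0.054 and PDR5 at -0.82 ± 0.054 (adjusted p = 0.000167; adjusted p = 0.123 with an estimated correlation). Of 7 trehalose genes 5 fell and 0 rose, with TSL1 at -0.83 ± 0.047 and TPS1 at -0.57 ± 0.043 (adjusted p = 0.000431; adjusted p = 0.11 with an estimated correlation). Hexose transporters had 6 falls and 1 rise of 14 (adjusted p = 0.00227; adjusted p = 0.13 with an estimated correlation). The mitochondrial ribosome had 27 rises and 1 fall of 55 (adjusted p = 0.00486; adjusted p = 0.423 with an estimated correlation). Histones had 5 rises and 0 falls of 7, HTB2 at 0.36 ± 0.04 (adjusted p = 0.0239; adjusted p = 0.378 with an estimated correlation), a call that also ended with median centring, with the 18S rRNA signal as a covariate and without scaling between arrays. The mitochondrial ribosome call ended without scaling, and the citric acid cycle call without the strain labelled a. With p-values adjusted over the list alone, 19 general stress genes, 30 amino acid genes and 9 citric acid cycle genes fell, and 17 RNA polymerase genes, 6 histone genes and 1 trehalose gene rose.

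Between 3% and 7% ethanol, amino acid genes fell throughout and most stress, chaperone and phospholipid genes rose. All 41 measured amino acid genes fell, with a median of -0.68, HIS4 at -2.16 ± 0.04 and HIS5 at -2.31 ± 0.059 (adjusted p = 9.54e-37; 0.0031 with an estimated correlation). CHA1 rose by 2.71 ± 0.064, CIT2 by 2.46 ± 0.064, INO1 by 2.38 ± 0.096, GIT1 by 2.28 ± 0.082 (3.03 with a pseudocount of 1) and HSP26 by 1.99 ± 0.059. SER3 was at -2.93 ± 0.061, STR3 at -2.49 ± 0.055, BIO3 of biotin synthesis at -1.94 ± 0.06 and ORT1, the mitochondrial ornithine carrier, at -1.88 ± 0.077. Of 39 lists 10 were called higher and 6 lower, and 9 held with an estimated correlation. In all, 2038 genes rose and 982 fell, 104 and 78 of them by at least 2-fold. With quantile normalization the counts were 1515 and 1469, with median centring 1219 and 1769.

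Of the general stress genes, 19 of 30 rose and 2 fell from 3% to 7%, with SPI1 at 1.96 ± 0.055 and HXK1 at 1.05 ± 0.039 (adjusted p = 0.00423; 0.0388 with an estimated correlation). That call ended when either haploid strain was left out. Ribosome biogenesis had 60 rises and 0 falls, with DBP2 at 1.49 ± 0.059 and YTM1 at 1.52 ± 0.067 (adjusted p = 2.61e-19), and the RNA polymerases 19 of 19 (adjusted p = 9.19e-06). Chaperones had 18 rises and 1 fall of 24, with HSP82 at 0.92 ± 0.05 (adjusted p = 0.000623). Phospholipid genes had 10 rises and 0 falls of 12 (adjusted p = 0.00423), and the endoplasmic reticulum response 13 and 0 of 15, with ERO1 at 0.95 ± 0.073 (adjusted p = 0.00423). Each of these 5 groups, ribosome biogenesis, polymerases, chaperones, phospholipids and endoplasmic reticulum, held at adjusted p = 0.0388 with an estimated correlation. Sulfur genes had 17 falls and 1 rise (adjusted p = 2.43e-09; 0.0186 with an estimated correlation), and ergosterol genes 14 falls and 1 rise (adjusted p = 8.51e-05; 0.0388 with an estimated correlation), a call that ended with quantile normalization. Cell wall genes had 19 rises and 3 falls of 27, with GSC2 at 1.89 ± 0.053 (adjusted p = 0.00423; adjusted p = 0.192 with an estimated correlation), and the mitochondrial ribosome 40 rises and 0 falls (adjusted p = 0.000373; adjusted p = 0.433 with an estimated correlation). Counted with p-values adjusted over the list alone, 19 chaperone genes and 43 mitochondrial ribosome genes rose.

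The largest changes within each strain were as follows. In the strain labelled alpha at 7%, FLO11 (YIR019C), a cell surface flocculin, rose by 4.34 ± 0.151 (20.3-fold, with signals of 29.8 and 908.6), CIT2 by 3.42 ± 0.111 and YRO2 by 3.36 ± 0.089, while HXT2 was at -4.84 ± 0.112 (28.6-fold lower, with signals of 1315 and 30.3), PRY3 at -3.93 ± 0.159 and SRY1 at -3.86 ± 0.086. Under the a label, CHA1 rose by 3.81 ± 0.11 (14-fold), INO1 by 3.63 ± 0.166 (12.4-fold) and CIT2 by 3.10 ± 0.111, while SER3 was at -3.49 ± 0.106 (11.2-fold lower), AQR1 at -3.34 ± 0.152 and PRY3 at -3.03 ± 0.159. In the diploid, YRO2 rose by 4.37 ± 0.089 (20.7-fold), HSP26 by 3.72 ± 0.102 (13.2-fold, with signals of 36.9 and 682.2) and NCA3 by 3.61 ± 0.103 (4.20 with a pseudocount of 1), while SRY1 was at -3.39 ± 0.086, TMT1 at -2.87 ± 0.111 and HIS5 at -2.74 ± 0.102. The numbers that rose and fell at 7% were 1445 and 1069 in the strain labelled alpha, 2596 and 811 in the strain labelled a, and 1954 and 1071 in the diploid. In the strain labelled a the median of all genes was 0.26 higher, and 1460 genes rose and 1439 fell with quantile normalization, 1330 and 1927 with median centring. In the diploid that median was 0.12 higher, with 1479 and 1524 by quantile normalization and 1301 and 1737 by median centring. For the strain labelled alpha it was 0.04 higher, with 1361 and 1254 by quantile normalization and 1184 and 1272 by median centring.

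The 3 strains shared much of the 7% response. 1035 genes rose in all 3 strains, where 255 would do so if the strains' calls were independent, and 495 fell in all 3, where 32.3 would. Independence is a low bar, as some genes may be called more readily in every strain. Sets of 35 and 132 genes were called in opposite directions in the 2 haploid strains. The correlation of the 7% changes across genes, which are not independent replicates, was 0.713 between the haploid strains, 0.822 between the strain labelled alpha and the diploid, and 0.843 between the strain labelled a and the diploid. Ribosome biogenesis had 58, 59 and 60 rises of 60 in the strains labelled alpha and a and in the diploid (adjusted p = 9.96e-21, 6.88e-18 and 4.59e-21). The call in the strain labelled a was lost at adjusted p = 0.0642 with an estimated correlation. Amino acid genes had 39, 36 and 38 falls of 41 (adjusted p = 1.53e-27, 1.46e-29 and 1.57e-25). The lists called higher and lower were 9 and 4 in the strain labelled alpha, 4 and 12 in the strain labelled a, and 7 and 6 in the diploid. Of these, 6, 2 and 4 held with an estimated correlation. The calls are relative to all other genes, and in the strain labelled a the median of all genes was 0.26 higher. Sulfur genes fell with a median of -1.23 in the strain labelled alpha (18 falls and 1 rise of 23, adjusted p = 1.66e-12) and -0.81 in the diploid (16 falls and 1 rise, adjusted p = 9.65e-09). In the strain labelled a the median was -0.17 (12 falls and 5 rises, adjusted p = 0.000424, lost at adjusted p = 0.0713 with an estimated correlation). Adjusted over the list alone, 59 ribosome biogenesis genes rose, 40 amino acid genes fell and 2 sulfur genes rose in the strain labelled alpha.

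At 3% the correlations of changes across genes were 0.524 between the haploid strains, 0.433 between the strain labelled alpha and the diploid, and 0.549 between the strain labelled a and the diploid. In the strain labelled alpha PHO84 rose by 2.02 ± 0.108 and YRO2 by 1.94 ± 0.089, while SNO1, of vitamin B6 synthesis, was at -2.50 ± 0.101 and SRY1 at -1.82 ± 0.086. Under the a label the zinc genes ZRT1 and ZPS1 rose by 2.40 ± 0.128 and 1.85 ± 0.11, while AQR1 was at -2.54 ± 0.152, HXT2 at -1.82 ± 0.112 and SOL4 at -1.71 ± 0.13. In the diploid YRO2 rose by 2.55 ± 0.089, HXT7 by 1.81 ± 0.165 and PUT1, of proline breakdown, by 1.74 ± 0.142, while HXT1 was at -2.31 ± 0.174 (-3.16 with a pseudocount of 1), HXT2 at -1.80 ± 0.112 and AQR1 at -1.77 ± 0.152. Ribosome biogenesis had 50 rises and 0 falls in the strain labelled alpha (adjusted p = 1.01e-24; 0.0227 with an estimated correlation) and 58 and 0 in the strain labelled a (adjusted p = 1.18e-17; 0.0372 with an estimated correlation). General stress genes had 15 falls and 3 rises in the strain labelled alpha (adjusted p = 5.6e-05; 0.0227 with an estimated correlation) and 19 and 0 in the strain labelled a (adjusted p = 2.75e-12; 0.000574 with an estimated correlation). The diploid had 6 rises and 2 falls in ribosome biogenesis, with a median of 0.10, and 6 rises and 1 fall among the general stress genes, with no call for either list. At 3%, 9 lists were called higher and 9 lower in the strain labelled alpha, 3 and 15 in the strain labelled a, and 2 and 5 in the diploid, of which 7, 6 and 0 held with an estimated correlation. The diploid's mitochondrial ribosome list had 24 rises and 0 falls of 55 (adjusted p = 3e-07; adjusted p = 0.435 with an estimated correlation). When adjusted over the list alone, 54 ribosome biogenesis genes rose and 16 general stress genes fell in the strain labelled alpha, and 59 rose (1 fell) and 20 fell in the strain labelled a. In the diploid 31 mitochondrial ribosome genes rose, 5 ribosome biogenesis genes rose and 2 fell, and 7 general stress genes rose and 4 fell.

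The counts at 3% were 673 rises and 675 falls in the strain labelled alpha, 1688 and 645 in the strain labelled a and 665 and 427 in the diploid. 149 genes rose in all 3 strains and 156 fell, where 26.3 and 6.46 would if calls were independent. In the 2 haploid strains, sets of 11 and 65 genes were called in opposite directions. In the strain labelled a the median of all genes was 0.12 higher, with 939 rises and 944 falls by quantile normalization and 870 and 1303 by median centring. In the diploid these were 503 and 500, and 536 and 551. Both smaller totals moved when 1 array was left out. The 1348 of the strain labelled alpha came to 838 without its 0% replicate 2 and 875 without its 3% replicate 2. The 1092 of the diploid came to 596 without its 0% replicate 1, 695 without its 3% replicate 1 and 550 without its 3% replicate 2. Without scaling between arrays the totals were 704, 1501 and 433.

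**Figure D3:**
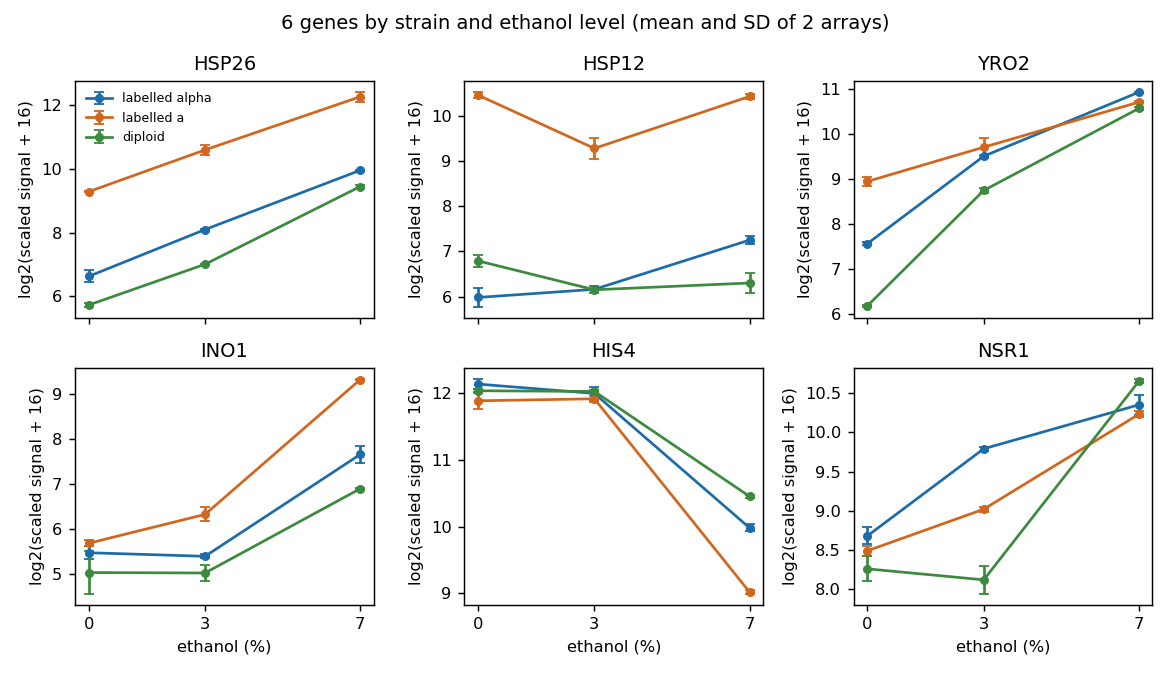
Log2 of the scaled signal plus 16 of 6 genes against ethanol level (%), as mean and SD of 2 arrays per strain and level. HSP26 climbs in every strain, from a mean signal of 83.8 to 981.4 in the strain labelled alpha, 610.3 to 4937 in the strain labelled a and 36.9 to 682.2 in the diploid.

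The next comparison asks how the diploid differs from the haploid strains; as there is 1 diploid strain, its ploidy and its other genetic differences cannot be separated. The diploid had lower levels of the transcripts of haploid cells and of alpha cells, and higher levels of amino acid genes. MF(ALPHA)1 differed from the mean of the haploids by -7.20 ± 0.058, AFB1 at -6.26 ± 0.045, STE3 at -5.91 ± 0.045 and MF(ALPHA)2 at -5.80 ± 0.056. FAR1, which arrests cells in pheromone, changed by -4.23 ± 0.06, HMLALPHA1 by -4.22 ± 0.047, the agglutinin SAG1 by -3.63 ± 0.046 and the G protein subunit GPA1 by -3.61 ± 0.058. As all of these but SAG1 are dim in the diploid, the size depends on the pseudocount: with 1 in place of 16, MF(ALPHA)1 was at -8.17, AFB1 at -7.52, STE3 at -7.38, MF(ALPHA)2 at -6.68, FAR1 at -5.21, HMLALPHA1 at -5.09 and GPA1 at -4.65. RME1, a repressor of meiosis, and the kinase FUS3 lay above the background limit on only 3 of 6 diploid arrays, so signals are given: 485, 860 and 5.09 for RME1 and 385, 273 and 6.42 for FUS3 in the strain labelled alpha, the strain labelled a and the diploid. HO, the mating-type endonuclease, was at least 8.53-fold lower in the diploid, and HMRA1 at least 7.4-fold higher. In the mean of the 3 ethanol levels 846 genes were higher in the diploid and 1317 lower, 14 and 56 by at least 2-fold. With quantile normalization the counts were 1221 and 918, with median centring 1331 and 858. The error of the fit is the spread between the 2 arrays of a group, so the difference between the 2 haploid strains is not in it. With the haploid arrays as 1 group and the ethanol level as a covariate, 507 genes were called.

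All 13 haploid-specific genes were lower (adjusted p = 3.53e-26; 0.000377 with an estimated correlation), and AMN1 was the least changed of those given here, at -0.94 ± 0.049. All 5 alpha-specific genes were lower (adjusted p = 1.56e-16; 0.000377 with an estimated correlation). Of 15 pheromone response genes 11 were lower and 0 higher, with AGA1 at -2.94 ± 0.083 (-3.56 with a pseudocount of 1) and SST2 at -2.30 ± 0.054 (adjusted p = 2.88e-08; 0.0129 with an estimated correlation). The a-specific list had 1 gene higher and 3 lower of 7, and the meiosis list 0 and 5 of 22, without a call. DSE2 and DSE1, daughter cell genes for separation after division, were higher by 2.71 ± 0.075 (6.52-fold) and 2.29 ± 0.086, the chitinase CTS1 by 1.23 ± 0.04 and the glucanase SCW11 by 1.32 ± 0.058. That list had 6 higher and 3 lower of 10 (adjusted p = 0.0192; adjusted p = 0.393 with an estimated correlation), and its call also ended with quantile normalization, with median centring and against the strain labelled a alone. Other genes higher in the diploid were UIP3 (2.17 ± 0.046), YAR068W (1.79 ± 0.073), PRY3 (1.78 ± 0.08), SRY1 (1.34 ± 0.043), the lactate dehydrogenase CYB2 (1.34 ± 0.066) and PRM8 (1.32 ± 0.1). UIP3 was nearly silent in the strain labelled alpha, and against the strain labelled a alone its difference was -0.84. With a pseudocount of 1 UIP3 was at 3.30, YAR068W at 3.19 and PRM8 at 2.24.

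Amino acid genes were higher in the diploid, 36 of 41 with 0 lower, LEU1 by 0.75 ± 0.038 and ILV2 by 0.43 ± 0.034 (adjusted p = 1.43e-23; 0.00571 with an estimated correlation). So were 15 of 22 ergosterol genes with 0 lower, HMG1 by 0.71 ± 0.056 (adjusted p = 3.3e-06; 0.0149 with an estimated correlation). Sulfur genes had 14 higher and 1 lower, with MET16 at 0.66 ± 0.053 (adjusted p = 2.84e-05; 0.0382 with an estimated correlation). Cell wall genes had 12 lower and 0 higher of 27, with DAN1 at -1.49 ± 0.036 and CWP1 at -0.96 ± 0.043 (adjusted p = 1.69e-06; 0.0382 with an estimated correlation). With p-values adjusted over the list alone, 12 pheromone genes were lower, 37 amino acid genes and 15 sulfur genes were higher, 48 ribosome biogenesis genes were lower, 28 ribosomal protein genes and 14 respiratory chain genes were higher.

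For 4 lists the sign of the median difference depends on which haploid is used. General stress genes had 20 lower and 4 higher of 30 against the mean of the haploids, with DDR2 at -2.68 ± 0.075 and HSP12 at -1.85 ± 0.065 (median -0.23, adjusted p = 0.000381; 0.0129 with an estimated correlation). Their median was -0.78 against the strain labelled a alone and 0.17 against the strain labelled alpha alone, where HSP12 was at -0.049 and no longer passed. Respiratory chain genes had 13 higher and 3 lower of 31, with CYC7 at 0.99 ± 0.051 and CYC1 at 0.88 ± 0.073 (adjusted p = 0.00111; adjusted p = 0.285 with an estimated correlation). Against the strain labelled a alone their median was -0.34, with CYC7 at -0.18 and CYC1 at -0.05. Ribosome biogenesis had 43 lower and 0 higher, with NSR1 at -0.42 ± 0.049 (adjusted p = 2.88e-08; adjusted p = 0.164 with an estimated correlation), and a median of 0.0073 against the strain labelled a alone. Ribosomal proteins had 29 higher and 1 lower of 128 (adjusted p = 3.3e-06; adjusted p = 0.604 with an estimated correlation), and a median of -0.028 against the strain labelled alpha alone. The respiratory chain and ribosomal protein calls also ended with quantile normalization.

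At 0% ethanol alone, 398 genes were higher and 570 lower in the diploid, 467 and 403 with quantile normalization and 562 and 407 with median centring. Of 39 lists 6 were called higher and 9 lower, and 7 held with an estimated correlation. The leading genes were DSE1 (2.55 ± 0.149), DSE2 (2.43 ± 0.13) and YAR068W (2.21 ± 0.127), and in the other direction MF(ALPHA)1 (-7.13 ± 0.1), AFB1 (-6.44 ± 0.078) and STE3 (-6.43 ± 0.077). With a pseudocount of 1 DSE1 was at 3.18, YAR068W at 3.63, MF(ALPHA)1 at -8.08, AFB1 at -7.81 and STE3 at -8.18. All 13 haploid-specific genes (adjusted p = 9.61e-05 with an estimated correlation) and all 5 alpha-specific genes (adjusted p = 2.2e-25; 6.47e-05 with an estimated correlation) were lower. Amino acid genes had 22 higher and 0 lower (adjusted p = 6.22e-14; 0.0176 with an estimated correlation), and ergosterol genes 8 and 0 (adjusted p = 1.21e-06; 0.0144 with an estimated correlation). General stress genes had 18 lower and 1 higher, with DDR2 at -3.20 ± 0.129 (median -0.39, adjusted p = 2.45e-12; 0.000209 with an estimated correlation), and a median of 0.19 against the strain labelled alpha alone. Cell wall genes had 12 lower and 0 higher, with DAN1 at -2.06 ± 0.062 (adjusted p = 1.21e-08; 0.0185 with an estimated correlation). The mitochondrial ribosome had 22 lower and 0 higher (adjusted p = 1.16e-08; adjusted p = 0.17 with an estimated correlation). The cell wall and mitochondrial ribosome calls ended against the strain labelled alpha alone, the ergosterol call against the strain labelled a alone. Counted with p-values adjusted over the list alone, 25 amino acid and 9 ergosterol genes were higher, 22 general stress genes lower and 2 higher, and 31 mitochondrial ribosome genes lower and 1 higher. The total of 968 genes came to 562 without the diploid 0% replicate 1, 627 without its replicate 2 and 457 without scaling between arrays. Against the strain labelled alpha alone it was 1465 and against the strain labelled a alone 1665.

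The haploid strains differed from each other in stress and respiration genes, which were lower in the strain labelled alpha, and in ribosome biogenesis genes, which were higher there. HSP12, a membrane stress protein, was lower there at -3.60 ± 0.075 (12.1-fold lower), the catalase CTT1 at -2.81 ± 0.123 and the glycogen phosphorylase GPH1 at -2.70 ± 0.055. YHB1, a flavohemoglobin that removes nitric oxide, was higher by 2.17 ± 0.046 (4.5-fold) in the strain labelled alpha. Some transcripts were at background in 1 of the haploid strains: MST27 was at least 36.8-fold higher in the strain labelled alpha and UIP3 at least 198-fold lower. In the mean of the 3 ethanol levels 1835 genes were higher and 1492 lower in the strain labelled alpha, 38 and 135 by at least 2-fold.

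Other genes higher in the strain labelled alpha were PRM9 (2.76 ± 0.07, or 4.29 with a pseudocount of 1), the drug transporter ATR1 (1.89 ± 0.054), the malic enzyme MAE1 (1.85 ± 0.06), the acid phosphatase PHO5 (1.67 ± 0.053) and the cell wall gene TIR4 (1.52 ± 0.048). AIM21 (1.51 ± 0.07), INM1 (1.35 ± 0.058) and AAH1 (1.34 ± 0.066) followed. Other genes lower there were STF2 (-2.71 ± 0.051), DDR2 (-2.56 ± 0.086), DCS2 (-2.52 ± 0.095), SNO1 (-2.52 ± 0.059), HSP26 (-2.49 ± 0.059), CYC7 (-2.32 ± 0.059) and GAD1 (-2.15 ± 0.058). General stress genes had 27 lower and 0 higher of 30, with a median of -1.14 (adjusted p = 1.58e-19; 8.14e-05 with an estimated correlation). All 31 respiratory chain genes were lower, RIP1 at -1.27 ± 0.043 and QCR7 at -1.16 ± 0.046 (adjusted p = 2.92e-20; 0.0103 with an estimated correlation). Of 55 mitochondrial ribosome genes 53 were lower and 0 higher, with MRP8 at -0.86 ± 0.053 (adjusted p = 2.65e-15; 0.0474 with an estimated correlation). Citric acid cycle genes had 14 lower and 0 higher of 16, with SDH1 at -1.03 ± 0.057 (adjusted p = 1.69e-07; 0.0103 with an estimated correlation). Glycogen genes had 10 lower and 0 higher of 11, with GSY2 at -1.80 ± 0.067 (adjusted p = 3.78e-07; 0.0103 with an estimated correlation). All 7 trehalose genes were lower, TSL1 at -1.48 ± 0.047 and TPS2 at -1.16 ± 0.044 (adjusted p = 1.81e-06; 0.0362 with an estimated correlation).

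Oxidative defence genes had 16 lower and 1 higher of 24, with TSA2 at -2.02 ± 0.079 (adjusted p = 3.07e-06; 0.0362 with an estimated correlation). Genes repressed by glucose had 15 lower and 1 higher of 21, with HXK1 at -0.95 ± 0.039 (adjusted p = 0.000111; 0.012 with an estimated correlation). Ribosome biogenesis went the other way, with 55 of 60 higher and 0 lower, NOP56 by 0.88 ± 0.052 and HAS1 by 1.21 ± 0.073 (adjusted p = 9.35e-15; 0.039 with an estimated correlation). RNA polymerase genes had 16 of 19 higher and 0 lower, with RPA135 at 0.89 ± 0.055 (adjusted p = 3.07e-06; 0.039 with an estimated correlation). 5 calls were lost with an estimated correlation. Ribosomal proteins had 102 higher and 0 lower of 128, with RPS0A at 0.34 ± 0.033 (adjusted p = 2.03e-08; adjusted p = 0.475 with an estimated correlation). Amino acid genes had 28 higher and 6 lower, with LEU1 at 0.79 ± 0.044 (adjusted p = 9.52e-05; adjusted p = 0.166 with an estimated correlation). Daughter separation genes had 9 lower and 1 higher of 10, with CTS1 at -1.53 ± 0.047 (adjusted p = 0.000877; adjusted p = 0.166 with an estimated correlation). Alpha-specific genes had 4 higher and 0 lower of 5, with SAG1 at 0.97 ± 0.053 (adjusted p = 0.0244; adjusted p = 0.0919 with an estimated correlation). Pheromone response genes had 9 higher and 1 lower of 15, with SST2 at 1.03 ± 0.062 (adjusted p = 0.0244; adjusted p = 0.204 with an estimated correlation). The alpha-specific and pheromone calls also ended with a pseudocount of 1. Adjusted over the list alone, 54 mitochondrial ribosome genes and 16 genes repressed by glucose were lower, and 107 ribosomal protein genes higher.

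Whether the ethanol response itself differs between strains was tested as a difference of changes. Such a difference depends on the strains' levels at 0% as much as on those in ethanol. Its error is the spread between the 2 arrays of a group, so variation of the response between strains is not in it. At 3% ethanol the diploid's response differed from that of the haploids: ribosome assembly rose less and stress and respiration genes were relatively higher. Ribosome biogenesis had 38 of 60 genes lower and 0 higher in this difference, with a median of -0.60, NSR1 at -0.96 ± 0.12 and BRX1 at -0.82 ± 0.102 (adjusted p = 4.89e-29; 0.014 with an estimated correlation). RNA polymerase genes had 11 of 19 lower and 0 higher, with RPA135 at -1.07 ± 0.118 (adjusted p = 1.4e-09; 0.0145 with an estimated correlation). General stress genes had 15 of 30 higher and 0 lower, with HXK1 at 1.14 ± 0.083 and PGM2 at 1.18 ± 0.103 (adjusted p = 7.25e-18, or 0.000119 with an estimated correlation). In the strains labelled alpha and a and the diploid, HXK1 read 571.7, 1429 and 338.5 at 0% and 721.7, 1512 and 883.8 at 3%. PGM2 read 1186, 2730 and 1654 at 0% and 382.7, 1906 and 1807 at 3%. Respiratory chain genes had 12 of 31 higher and 0 lower, with COR1 at 0.45 ± 0.096 (adjusted p = 9.64e-11; 0.0318 with an estimated correlation), though COR1 no longer passed without scaling between arrays. With an estimated correlation the citric acid cycle (5 higher and 0 lower), glycogen (4 and 0, GSY2 at 0.95 ± 0.142), oxidative defence (7 and 0, TSA2 at 1.30 ± 0.167) and glucose-repressed (3 and 0) lists also passed, at adjusted p = 0.014, 0.014, 0.0339 and 0.0374. In all, 9 lists were called higher and 3 lower, and these 8 held. Against the strain labelled alpha alone the citric acid cycle and glucose-repressed calls ended. RGI1 had the largest positive difference at 1.92 ± 0.099, then CYB2 (1.70 ± 0.163) and SUE1 (1.61 ± 0.192, or 2.89 with a pseudocount of 1). HXT1 (-1.45 ± 0.213), ZRT1 (-1.44 ± 0.157) and URA7 (-1.20 ± 0.122) were the most negative, ZRT1 at -0.36 and not past the threshold against the strain labelled alpha alone. When adjusted over the list alone, 50 ribosome biogenesis and 14 RNA polymerase genes were lower, and 22 general stress, 16 respiratory chain, 8 citric acid cycle, 9 glycogen, 10 oxidative defence and 4 glucose-repressed genes higher.

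In number, 215 genes had a higher and 265 a lower 3% response in the diploid, 240 and 263 with quantile normalization and 286 and 214 with median centring. The total of 480 came to 297 without the diploid 0% replicate 1, 302 without its 3% replicate 1, 290 without its 3% replicate 2 and 203 without scaling between arrays.

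At 7% ethanol the diploid's response had higher differences in YRO2 (1.81 ± 0.109), HUG1 (1.63 ± 0.177), a gene of the DNA damage response, and SNZ1 (1.55 ± 0.084), and lower ones in FLO11 (-2.13 ± 0.185), PRM5 (-1.55 ± 0.131) and HXT1 (-1.52 ± 0.213). In the strains labelled alpha and a and the diploid, YRO2 read 172.9, 474.2 and 56.7 at 0% and 1920, 1649 and 1492 at 7%. Its difference thus came from the diploid's low level at 0%. SNZ1 read 3523, 4956 and 4690 at 0% and 249, 2346 and 2591 at 7%. FLO11 read 29.8, 65.7 and 40.1 at 0% and 908.6, 38.5 and 30.7 at 7%. Against the strain labelled a alone FLO11 was at 0.33 and SNZ1 at 0.22, where it no longer passed. Of 55 mitochondrial ribosome genes 26 were higher and 0 lower, with MRPL19 at 0.76 ± 0.108 (adjusted p = 2.96e-17; adjusted p = 0.106 with an estimated correlation); MRPL19 was at 0.67 and no longer past the threshold without scaling between arrays. In all, 6 lists were called higher and 3 lower in this difference, and 0 held with an estimated correlation. Of 16 drug transporter genes 9 were lower and 1 higher, with PDR5 at -0.67 ± 0.114 (adjusted p = 7.94e-07; adjusted p = 0.106 with an estimated correlation). With p-values adjusted over the list alone, 36 and 11 genes moved in these directions. 256 genes were higher and 238 lower, 494 in all. The total came to 245 without the diploid 0% replicate 1, 299 without its 7% replicate 1, 240 without its 7% replicate 2 and 140 without scaling between arrays. Against the strain labelled alpha alone it was 1010, and against the strain labelled a alone 849.

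The 7% responses of the haploid strains differed in several gene groups. Relative to all other genes, 18 of 39 lists were called higher and 4 lower in the strain labelled alpha. Of these, 6 and 1 held with an estimated correlation. As the median difference of all genes was -0.21, a list called higher can hold few genes that were higher themselves. FLO11 had a difference of 4.94 ± 0.214 (30.6-fold; 5.67 with a pseudocount of 1) in favour of the strain labelled alpha, YER053C-A 2.28 ± 0.153 and YRO2 1.59 ± 0.125, while HXT2 was at -3.81 ± 0.158, MET3 at -2.96 ± 0.153 and SNZ1 at -2.67 ± 0.097. Of 23 sulfur genes 15 were lower and 1 higher in the difference, with MET10 at -2.20 ± 0.126 and a median of -1.01 (adjusted p = 1.22e-05; 0.0401 with an estimated correlation). The mitochondrial ribosome had 30 lower and 0 higher, with MRP13 at -1.05 ± 0.154 (adjusted p = 0.000412; adjusted p = 0.278 with an estimated correlation). The 6 lists called higher that held with an estimated correlation were alpha-specific (4 higher and 0 lower of 5, adjusted p = 2.59e-05), chaperones (3 and 1 of 24, adjusted p = 0.000351), general stress (9 and 5 of 30, adjusted p = 0.000506), the citric acid cycle (5 and 0 of 16, adjusted p = 0.000331), ergosterol (8 and 1 of 22, adjusted p = 0.000118) and the endoplasmic reticulum response (6 and 2 of 15, adjusted p = 0.000907). Their adjusted p-values with an estimated correlation were 0.0377 for alpha-specific and general stress genes and 0.0401 for the others. With quantile normalization the chaperone, general stress, citric acid cycle and ergosterol calls ended, and the ergosterol median went from 0.10 to -0.038. Ribosome biogenesis had 35 lower and 1 higher, with BRX1 at -1.09 ± 0.117 (adjusted p = 0.00133; adjusted p = 0.278 with an estimated correlation), a call that ended with quantile normalization. Counted with p-values adjusted over the list alone, 31 mitochondrial ribosome and 37 ribosome biogenesis genes were lower, 2 ergosterol genes were lower and 8 endoplasmic reticulum genes higher. In all 397 genes were higher and 1637 lower, with a median of all genes of -0.21. That total of 2034 was 1104 with quantile normalization, 557 higher and 547 lower, and median centring gave 1110 higher and 610 lower. With median centring the list medians were -0.73 for sulfur, -0.21 for the mitochondrial ribosome and -0.18 for ribosome biogenesis.

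At 3% the difference between the haploid responses was positive in FMP45 (1.40 ± 0.199), HSP12 (1.35 ± 0.184) and RPI1 (1.33 ± 0.152), and negative in the zinc genes ZRT1 (-2.15 ± 0.181) and ZPS1 (-1.89 ± 0.156) and in YGR035C (-1.59 ± 0.179). The list of 7 ploidy-dependent genes had 5 higher and 0 lower, with the G1 cyclin CLN3 at 1.02 ± 0.165 (adjusted p = 1.36e-06; 0.0462 with an estimated correlation). General stress genes had 7 higher and 2 lower (adjusted p = 0.00163; 0.0462 with an estimated correlation), a call that ended with quantile normalization. Citric acid cycle genes had 4 higher and 0 lower of 16 (adjusted p = 2.34e-05; 0.0462 with an estimated correlation). In all, 8 lists were called higher and 2 lower, and these 3 held with an estimated correlation. The mitochondrial ribosome had 22 lower and 0 higher (adjusted p = 0.000152; adjusted p = 0.348 with an estimated correlation). Adjusted over the list alone, 6 ploidy-dependent genes were higher, and 25 mitochondrial ribosome genes lower and 1 higher. In all 193 genes were higher and 818 lower, with a median of all genes of -0.12; the counts were 273 and 351 with quantile normalization and 579 and 326 with median centring. The total of 1011 came to 624 with quantile normalization, 353 without scaling between arrays, 648 in a fit of the compared groups only, 609 without the alpha 0% replicate 2 and 637 without the alpha 3% replicate 2.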

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

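Of the tests in this part, those of the mating type of the strain labelled a and of each haploid strain in the 3% difference were chosen only after the result was seen, and the 18S rRNA covariate after the data but before its result was seen.

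Differences of the ethanol response between strains, each tested as a difference of changes, drew attention first. At 7% ethanol 494 genes differed between the diploid and the mean of the haploids and at 3% 480. Between the strains labelled alpha and a, 2034 genes differed at 7% and 1011 at 3%. The error of these counts leaves out variation of the response between strains. At 7% the changes correlated least between the haploid strains, 0.713 against 0.822 and 0.843 with the diploid. At 3% these were 0.524, 0.433 and 0.549. The counts therefore do not set the diploid's 7% response apart from differences between strains in general. For the diploid minus the haploids at 7%, the log2 differences were 1.81 for YRO2, 1.63 for HUG1, 1.55 for SNZ1, -2.13 for FLO11, -1.55 for PRM5 and -1.52 for HXT1. For the same strains at 3% they were 1.92 for RGI1, 1.70 for CYB2, 1.61 for SUE1, -1.45 for HXT1, -1.44 for ZRT1 and -1.20 for URA7. For alpha minus the strain labelled a at 7% they were 4.94 for FLO11, 2.28 for YER053C-A, 1.59 for YRO2, -3.81 for HXT2, -2.96 for MET3 and -2.67 for SNZ1. At 3% they were 1.40 for FMP45, 1.35 for HSP12, 1.33 for RPI1, -2.15 for ZRT1, -1.89 for ZPS1 and -1.59 for YGR035C. Outside the genes tested, 149 of 704 probe sets without a gene name here passed the threshold at 7% against 0%, 97 up and 52 down. Their species is not given in the annotation, so some may be probe sets of the other yeast.

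Alpha-specific transcripts were high in the strain labelled a, and alpha arrays deposited under its label are argued against by 14 genes at least 4-fold apart between the haploid strains in the same direction at all 3 ethanol levels. RNA of the alpha strain mixed into the a samples is argued against by 47 of 4616 genes bright in alpha, whose ratio to alpha lay below the lowest ratio of the alpha-specific genes, 0.485; MST27 was at 0.00259. The probe set of alpha1 was 35-fold brighter in the strain labelled a than in the diploid, so a strain that expresses the MAT alpha locus is a candidate explanation. The a-specific AGA2, MFA1 and MFA2 had mean signals of 15.3, 18.8 and 30.8 in the strain labelled a and 5.21, 8.63 and 21.5 in alpha, where AGA2 passed the background limit on 2 of 6 arrays; a minor share of a cells or their RNA was not tested and stays open. Also open, as untested, are a mix-up outside these samples and a probe set failure of the a-specific genes, which no strain here is shown to express at a high level.

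More genes rose than fell at 7% in the strain labelled a, by the trimmed mean scaling. Relative to the hybridisation spike-in controls its median of all genes moved by 0.375 from 0% to 7% (estimate ± 2 SE -0.018 to 0.768), against 0.056 in the strain labelled alpha and 0.065 in the diploid. The range holds both no shift and a shift of the size seen, so a true shift and an effect of scaling cannot be told apart. A narrower range would not decide it either, as controls of the hybridisation step do not measure the amount of RNA per cell. Either could account for the balance. On single arrays of the strain labelled a, the median minus the spike-in controls was -2.44 and -1.90 at 0% and -1.90 and -1.69 at 7%. The size of the shift thus depends on which 0% array is used.

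Ribosome biogenesis genes responded less to 3% ethanol in the diploid than in the haploids. A difference in 18S rRNA carry-over is argued against, as the list median of the difference was -0.619 with the 18S control signal as a covariate. An array that sets the difference alone is argued against, since the median was -0.644 to -0.497 without each array in turn. A haploid strain that sets it alone is argued against, since it was -0.671 and -0.445 against each haploid strain. A difference by ploidy or another difference of the diploid strain may remain as a hypothesis, and neither was tested, as there is 1 diploid strain.

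Random splits address whether arrays grouped at random, with the other factor as a covariate, give as many genes. For 7% against 0% the real split called 3230 genes and the highest other split 805, for 3% against 0% 1782 and 851, for 7% against 3% 2572 and 773, and for the haploid strains against each other 2572 and 913. In these contrasts 1 of 100 splits, the real one, was as large, which is the smallest share that 100 splits can give. The splits handle the 2 arrays of a group as separate samples. As the labels do not say whether these came from separate cultures, the share does not exclude chance differences between cultures. The median of the other splits was 0 genes, and a true effect left within the groups of a random split adds to its spread, so the share does not measure how strong a contrast is. For the diploid against the haploids the real split called 507 and the highest other 1078, and 2 of 100 splits were as large. That share is under 0.05, but an arbitrary split called more genes than the real one, so this count sets the contrast apart less firmly. The higher split set 5 alpha arrays and 1 array of the strain labelled a against the rest, and so largely parted alpha from the others.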

How the results depend on the processing

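Unscaled values, the 18S rRNA covariate and leaving out each haploid strain were chosen after the data were seen; the others were fixed before the data were examined. Of 259 gene results, 3695 of 3704 values under the alternatives kept direction and side of the threshold, 5 lost the threshold and 4 reversed. All 2948 values with 1 array left out kept both. These genes were picked in the same data for a large change or a small adjusted p, and all passed the threshold. Their stability was therefore likely beforehand and does not stand for genes near the threshold, whose counts moved as given below. Of 110 list results, 71 held with an estimated correlation, 98 with quantile normalization, 107 with median centring, 106 unscaled and 109 with the 18S covariate. Of 68 list results that could be run, 57 held without the strain labelled a (8 lost, 3 reversed) and 60 without alpha (6 lost, 2 reversed). AGA2 had no value under the stricter filter. With the replicate block 259 of 259 gene results and 110 of 110 list results held, and the block count of 7% against 0% was 3786.

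Unscaled, the counts were 704, 1501 and 433 for 3% against 0% in the strains labelled alpha and a and the diploid, 457 for the diploid at 0%, 140 and 203 for the diploid's 7% and 3% differences and 353 for the haploids' 3% difference. Quantile normalization gave 1104 and 624 for the haploids' 7% and 3% differences, and a fit of the compared groups 648 for the latter. Without the strain labelled a the diploid at 0% gave 1465 and its 7% difference 1010; without alpha these were 1665 and 849. With 1 array left out, which assumes that the lone array of a group varies like the others, counts were 838 to 1061 for 3% in alpha, 550 to 872 in the diploid, 562 to 897 for the diploid at 0%, 240 to 512 and 290 to 575 for the diploid's 7% and 3% differences and 609 to 952 for the haploids' 3% difference. For these moves the cause was not tested.

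Reversed without alpha, for the diploid against the haploids: UIP3 -0.841, CYC7 -0.176, CYC1 -0.05, respiratory chain -0.34 and ribosome biogenesis 0.00734, and FLO11 at 0.334 in the 7% difference. Without the strain labelled a general stress was 0.168 (0.187 at 0%) and ribosomal proteins -0.0278. These alternatives set the diploid against 1 haploid strain in place of the mean of both. Signal over background limits 86 genes, which were too dim to test.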

Other observations

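The test of copy number in this part was chosen after the result was seen.

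For 6 genes outside the mating-type and pheromone lists the mean signal was under 11.4, or 2 times the mean background limit, in 1 haploid strain and over 45.6 in the other. MST27 had a mean signal of 200 (n = 6 arrays) in the strain labelled alpha, 0.518 in the strain labelled a and 92.1 in the diploid, and PRM9 134, 5.84 and 64.5. UIP3 read 2.83 in the strain labelled alpha, 1210 in the strain labelled a and 672 in the diploid. YAR068W, HMX1 and SUE1 read 1.87, 9.34 and 6.59 in the strain labelled alpha and 118, 37.8 and 48 in the diploid. HMX1 and SUE1 at 0% and 7% ethanol lay under 11.4 but above the background limit of the arrays, at most 7.58, so they were dim rather than silent.

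A candidate explanation is that the diploid carries 1 expressed copy from that haploid's lineage, which would put its signal near 0.5 of the haploid's; the parents of the diploid are not given in the sources used here, and both haploids had alpha-specific transcripts. The median ratio of diploid to expressing haploid over the 6 genes was 0.642 with quartiles of 0.5 and 0.866, and 3 of 6 lay between 0.35 and 0.65. Of 2549 genes expressed alike in both haploids the median ratio was 0.983, with 28 in that range. Of the 6 genes, UIP3 at 0.554, PRM9 at 0.482 and MST27 at 0.46 lay within the range. YAR068W at 1.87 lay far outside it, as did HMX1 at 0.729 and SUE1 at 0.912 by less, the 2 that were dim rather than silent. With 6 genes the test does not decide.

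Probe sets without a gene name or species here also differed in other contrasts. Of 704 tested, 99 passed at 3% against 0% (62 up, 37 down), 74 in the diploid against the haploids (30 up, 44 down) and 129 between the haploid strains (46 up, 83 down).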
